A study of Schizosaccharomyces pombe with 10 samples.

How the data were processed

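Poly(A)-selected RNA of Schizosaccharomyces pombe was sequenced on a NovaSeq instrument in 10 libraries. Per the labels, cells grew in rich medium to exponential phase, and RNA was extracted with hot acidic phenol and cleaned on columns. The 5 strains with 2 libraries each were wt (the parent with his3, ura4, leu1 and ade6 alleles), cph1Δ and cph2Δ made from it, wt2 (a second parent) and set2Δ made from that one. Deletions carried a kanamycin resistance marker. Groups were taken from the sample labels, and nothing in them says whether the 2 libraries of a strain came from separate cultures.

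Per the authors' processing notes, reads were aligned with STAR 2.7.10a to build ASM294v2, handled with SAMtools 1.16.1 and Picard, and counted with featureCounts of Subread 2.0.1; DESeq2 1.36.0 and edgeR 3.38.4 were named for the later steps. The deposited values are raw counts per gene, with a column of exon length in bases. Per the file headers, featureCounts counted exons summed by gene, with no option for strand, paired ends, multi-mapping reads, reads over several genes or duplicates. Reads of near-identical copies and of overlapping genes were therefore largely left unassigned, and the strand of origin is not known. Values of genes that share exon positions with another gene, and of Tf2 and wtf copies, are reported as uncertain.

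The tables held 7268 genes, of which 5691 had a count. Names and positions came from the files, and names were looked up in a RefSeq gene table, which matched 6862 identifiers and left 406; 6815 of the matched genes (99.3%) had the same start or end. Assigned counts per library were 10101062 and 11213099 in wt, 11778215 and 10030848 in cph1Δ, 9883590 and 13051467 in cph2Δ, 12020496 and 9711537 in wt2, and 9984911 and 12841976 in set2Δ. Replicates differed by more than counting error, with a chi-square per degree of freedom from 43.6 in wt2 to 130 in cph1Δ, so no library was a copy of another. The first 2 principal components held 31.2% and 23.6% of the variance.

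Differences were tested with edgeR 4.0.16 (limma 3.58.1) in R 4.3.3. Genes were kept by filterByExpr on the groups, which left 5067, 4409 of them coding and 599 non-coding RNAs; the 2201 genes removed held 0.0105% of the counts. Libraries were scaled by TMM, with factors from 0.846 in wt replicate 2 to 1.25 in cph1Δ replicate 2. The 5 groups were fitted together with 1 mean per group and no block, leaving 5 residual degrees of freedom, and quasi-likelihood F-tests (robust option off) were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. This is called the edgeR adjusted p. The common biological coefficient of variation was 0.211. The comparisons were cph1Δ with wt, cph2Δ with wt, set2Δ with wt2, cph1Δ with cph2Δ, the difference of the cph1Δ and of the cph2Δ effect from that of set2Δ, and wt2 with wt. Standard errors were the size of the log2 fold change over the square root of F. Genes changed at least 2-fold were those past the test with a log2 fold change of at least 1 in size. A fold against a group of 0 counts was given as a lower bound with a floor of 3 counts over the group, and ratios of 1 to 3 counts with a 95% counting interval.

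Gene lists fixed before the counts were seen were tested with camera at a preset correlation of 0.01 between genes and adjusted by Benjamini-Hochberg over the lists of a comparison, the camera adjusted p. An estimated correlation and the rotation test fry were run beside it. There were 34 lists in the deletion comparisons and 33 in the others, which have no list of neighbours of a deleted gene. They covered chromatin and elongation factors, repeats, subtelomeric genes (within 100 kb of an end of chromosome I or II), the 3 coding genes on each side of a deletion, non-coding RNAs, stress, nutrient, mating and meiotic genes, and housekeeping groups. Members were also adjusted over the list alone. Lists that passed in a deletion were compared, after the calls were seen, with 10000 random lists of tested genes matched in exon length and in level in wt2. Matching was by bins of length and level, and genes were drawn independently. Differences in level within a bin, and genes of a list that vary together, were therefore not matched. A list needed 3 tested members.

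The rule for named genes was set before the counts were seen. It took the 3 deleted genes and the markers, and in each main comparison the 8 largest rises and 8 largest decreases past the test with a mean of at least 5 CPM over the 4 compared libraries and both deletion libraries beyond both parent libraries. Markers, the deleted gene and repeat copies were left out of these. It also took up to 4 members of each list that passed and of the Tf2, subtelomeric, heterochromatin, elongation and Clr6 lists, 5 per direction in the other comparisons, and 5 per direction among genes called in all 3 strains. Genes between mat1 and mat3, genes under the lower-bound rule, other members of the lists, and the genes called between the parents or between cph1Δ and cph2Δ were added after their values were seen.

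The overlap of calls was compared with independent lists by Fisher's exact test and, for the shared wt libraries, with 25 simulated draws of unchanged groups. Spearman correlations of log2 fold change with exon length and with the parent's level were taken across coding genes. The steps were tested on simulated data with 200 changed genes added. In cph1Δ, cph2Δ and set2Δ (5023, 5028 and 5003 genes) edgeR recovered 47%, 47% and 56% of the 2-fold changes and 88%, 90% and 89% of the 4-fold ones, with 6.21%, 0% and 5.77% false calls. DESeq2 1.42.0 on 5067 genes recovered 66%, 62% and 60% at 2-fold, with 14.4%, 7.56% and 8.38% false calls. A list of 30 genes shifted 1.5-fold passed in each, and 0 of 20 unshifted lists did. Genes were drawn independently of each other, so this could not show how often lists of correlated genes pass at the preset correlation.

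Alternatives planned before the counts were seen were RLE scaling, no filter, a fit of the compared libraries only, coding genes only, leaving out each library, a replicate block, DESeq2, an estimated correlation, fry, and length and level relations without genes near chromosome ends. Chosen after seeing the data were the level in the other parent, set2Δ without subtelomeric genes, cph2Δ without the genes between mat1 and mat3, and coding genes over 5 kb as a list. Python 3.11.15 and matplotlib 3.10.9 made the tables and figures. Reads were not used here. The values of 1 gene that the naming rule took are not reported here.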

Results

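Messenger RNA levels were measured by poly(A)-selected RNA sequencing in 10 libraries of the fission yeast Schizosaccharomyces pombe. The libraries came from 5 strains with 2 libraries each. The strain called wt here was the parent of the cph1 and cph2 deletion strains (cph1Δ, cph2Δ), and a second parent, wt2, was that of the set2 deletion strain (set2Δ). Cph1 and Cph2 are PHD finger subunits of Clr6 complex II, the fission yeast counterpart of the Rpd3S histone deacetylase, and Set2 is the methyltransferase of histone H3 lysine 36. The comparisons ask how the loss of factors that act on chromatin behind elongating RNA polymerase II, changed the transcriptome. Depth lay between 9711537 and 13051467 assigned counts per library, and 5067 of 7268 annotated genes had enough counts to be tested. Errors of log2 fold changes are standard errors of the fit with n = 2 libraries per group, and levels are CPM ± SD with n = 2. Nothing in the labels says that replicates were separate cultures, so the p-values of genes measure only the spread between these libraries. Camera sets the genes of a list against the other genes at a preset correlation, and Fisher's exact test treats genes as independent. The p-values of these 2 tests are therefore not evidence across cultures. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 5067 genes, and those of gene lists are from camera with adjustment over the lists. Coordinates are on build ASM294v2.

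The deleted genes were examined as a check of the labels. The cph1 gene (SPAC16C9.05, chromosome I, 799341 to 800981) stood at 80.3 ± 1.37 CPM in wt and 3.48 ± 1.19 CPM in cph1Δ, or 4.34% of the parent's level (log2 fold change -4.53 ± 0.24, edgeR adjusted p = 2.5e-06). Its level was 128 ± 15.9 CPM in cph2Δ, 97.0 ± 4.39 CPM in wt2 and 132 ± 2.63 CPM in set2Δ. The cph2 gene (SPAC2F7.07c, chromosome I, 544127 to 546240) stood at 124 ± 15.1 CPM in wt and 4.66 ± 3.24 CPM in cph2Δ, which left 3.72% (-4.75 ± 0.39, edgeR adjusted p = 3.9e-04). In the other strains cph2 was at 157 ± 48.1 CPM in cph1Δ, 130 ± 10.5 CPM in wt2 and 157 ± 9.50 CPM in set2Δ. The set2 gene (SPAC29B12.02c, chromosome I, 5408180 to 5411132) stood at 106 ± 5.39 CPM in wt2 and 8.43 ± 0.247 CPM in set2Δ, leaving 7.97% (-3.65 ± 0.17, edgeR adjusted p = 7.7e-07). It was at 104 ± 0.520 CPM in wt, 144 ± 2.84 CPM in cph1Δ and 145 ± 10.05 CPM in cph2Δ. No library went against its label at these 3 deleted genes. Among the marker genes named in the genotype of the wt background, ura4 had 0 counts in all 6 libraries of wt, cph1Δ and cph2Δ, against 142 ± 0.154 CPM in wt2 and 186 ± 8.34 CPM in set2Δ. The his3 gene had between 0 and 5 counts in each of the 10 libraries, also in wt2 and set2Δ, whose labels list no his3 allele. Counts of leu1 and ade6 were high in every library, with leu1 at 674 ± 151 CPM in wt and 636 ± 30.6 CPM in wt2.

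**Figure D1:**
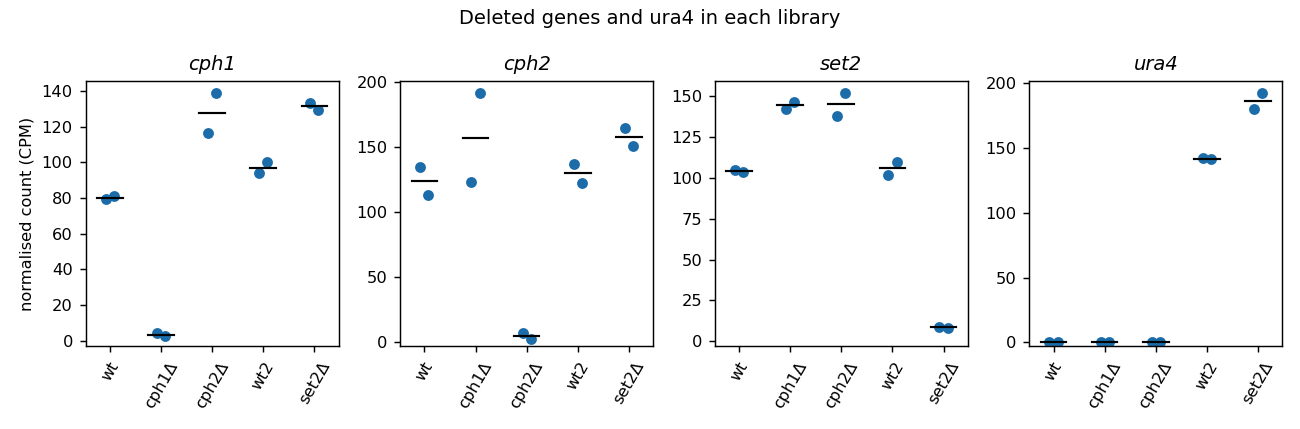
Normalised counts (CPM, linear axis) of cph1, cph2, set2 and ura4 in each of the 10 libraries, as points, with the mean of the 2 libraries of a strain as a line. Each deleted gene lies under 10 CPM in both libraries of its own deletion strain, and ura4 lies at 0 in wt, cph1Δ and cph2Δ.

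Deletion of cph1 was followed mainly by higher transcript levels, among them genes normally kept silent in growing cells. The meiotic cohesin gene rec8 (SPBC29A10.14, chromosome II, 2568893 to 2570993) rose by 2.95 ± 0.49 on the log2 scale, and mek1 (SPAC14C4.03, chromosome I, 5231140 to 5232566), a meiosis-specific kinase gene, rose by 2.68 ± 0.41. The lipid transfer protein gene vps1301 (SPBC21C3.01c, chromosome II, 3788890 to 3798775) rose by 2.33 ± 0.22, and the chromatin remodeller gene mit1, of the heterochromatin list, rose by 1.68 ± 0.24. The phosphate transporter gene pho84 (SPBC8E4.01c, chromosome II, 4444125 to 4446200) fell by 1.78 on the log2 scale (SE 0.29), and the glucose transporter gene ght5 (SPCC1235.14, chromosome III, 212160 to 214376) fell by 1.66 (SE 0.32). In all, 285 genes differed between cph1Δ and wt (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 269 higher and 16 lower, and 164 of them by at least 2-fold, 153 higher and 11 lower.

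The largest fitted rise among genes above 5 CPM was that of the non-coding RNA SPNCRNA.234 (chromosome I, 3786105 to 3787136) at 4.67 ± 0.999, from 0 and 11 counts in wt to 166 and 197 in cph1Δ (edgeR adjusted p = 0.020). It was followed by SPNCRNA.1153 (3.59 ± 0.93), rec8 and the pseudogene SPCC663.07c (2.89 ± 0.73). Counts of 2 of these were uneven in cph1Δ, at 84 and 1675 for SPNCRNA.1153 and 251 and 2615 for SPCC663.07c. The gene dli1, for a meiotic dynein light intermediate chain, stood at 2.83 ± 0.63, and SPBC609.01, of the Dis3-like exonuclease family, at 2.36 ± 0.29. On the other side, pfl7, of the flocculin-like family, had -2.76 ± 0.69, the chromosome end gene SPBPB10D8.01 had -2.41 ± 0.42, and SPAC2H10.01 had -2.37 ± 0.62 with 759 and 5070 counts in the wt libraries. The acid phosphatase gene pho1 (-1.48 ± 0.29), the gene abp2, for a protein that binds replication origins (-1.22 ± 0.28), and emc5 (-1.10 ± 0.27) completed the named decreases. Some of these genes were also lower in the undeleted wt2 than in wt, namely SPBPB10D8.01 (-3.16), pho1 (-1.20, not past the test), abp2 and pfl7. For them wt stood above both strains. Counting took no account of strand, and SPNCRNA.1153, SPCC663.07c, dli1, SPBC609.01, vps1301, pfl7, SPBPB10D8.01, pho84, abp2 and emc5 share exon positions with another gene, so the values of these 10 genes are uncertain. The same holds for mit1, dcr1, rdp1, rec10, spo5, byr2, sxa2, mug125, SPNCRNA.662, SPNCRNA.1191, rpl2001, cys11, atp4, hht3 and fft2 named from the lists.

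Heterochromatin and RNA interference factors were higher in cph1Δ as a list, and genes matched in length and level shared a part of this rise. Random lists of such genes had a median of 0.41, and the list lay at percentile 96.84 of them. Of 16 members tested, 7 rose and 9 did not pass over all genes, 10 rose when adjusted over the list alone, and the median log2 fold change was 0.70 (camera adjusted p = 7.4e-08; adjusted p = 0.459 with an estimated correlation). Besides mit1, these included the Dicer gene dcr1 (1.08 ± 0.16) and the RNA-dependent RNA polymerase gene rdp1 (1.06 ± 0.18). A further list joined meiotic genes in general with transcripts removed by Mmi1 in growing cells, and is called meiotic transcripts here. Of its 10 tested members, 5 rose, 7 when adjusted over the list alone. The median was 1.88 (camera adjusted p = 4.7e-07; adjusted p = 0.459 with an estimated correlation). They included rec10, a meiotic recombination gene (1.76 ± 0.36), and spo5, a meiotic RNA-binding protein gene (2.25 ± 0.50). Of 80 members of the mug and meu families, 11 rose, 13 when adjusted over the list alone, among them mug184 (1.57 ± 0.20) and mug125 (1.56 ± 0.25). The median was 0.32 (camera adjusted p = 0.00853; adjusted p = 0.555 with an estimated correlation). Among 22 mating and pheromone genes, 5 rose, or 8 higher and 1 lower when adjusted over the list alone, including the kinase gene byr2 (1.77 ± 0.23), the carboxypeptidase gene sxa2 (1.37 ± 0.24), map4 (1.12 ± 0.20) and ste7 (1.158 ± 0.247). Their median was 0.71 (camera adjusted p = 0.00484; adjusted p = 0.555 with an estimated correlation).

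The 13 Tf2 retrotransposon copies had a median of 1.90, with 3 copies higher over all genes and 8 when adjusted over the list alone (camera adjusted p = 2.3e-06; adjusted p = 0.459 with an estimated correlation). Their values per copy are uncertain because the copies are nearly identical; Tf2-11 had 2.55 ± 0.43, Tf2-8 3.17 ± 0.72 and Tf2-2 2.01 ± 0.47. Of 25 wtf genes, likewise similar copies, 2 were higher, 3 when adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.0484; adjusted p = 0.669 with an estimated correlation). Their examples are wtf24 (1.157 ± 0.266) and wtf8 (1.47 ± 0.36). Of 320 non-coding RNAs antisense to a coding gene, 6 rose and 0 passed when adjusted over the list alone. The median was 0.39 (camera adjusted p = 0.0224; adjusted p = 0.659 with an estimated correlation). SPNCRNA.662 (2.08 ± 0.38) and SPNCRNA.1191 (1.164 ± 0.249) led them, and reads from such a pair cannot be assigned to a strand here. In the DNA damage list, rad50 (1.90 ± 0.30), which shares exon positions with its neighbour, and rad54 (0.87 ± 0.17) rose among 13 members, 4 when adjusted over the list alone. The median was 0.26 (camera adjusted p = 0.0379; adjusted p = 0.555 with an estimated correlation). In the thiamine list, thi5 (0.85 ± 0.20) rose among 6 members, 5 when adjusted over the list alone. The median was 0.51 (camera adjusted p = 0.0379; adjusted p = 0.459 with an estimated correlation). Against 10000 random lists matched in length and level, the DNA damage median lay at percentile 29.1 (matched median 0.37) and that of the wtf genes at 52.55 (0.30), so neither stood above its matched genes. The mug and meu families lay at percentile 94.2 and the thiamine list at 93.4. Tf2 copies lay at percentile 99.8 (matched median 0.85) and antisense non-coding RNAs at 97.16 (0.30). Mating genes lay at 99.79 (0.29) and meiotic transcripts at 100 (0.34). Medians against wt in replicates 1 and 2 of cph1Δ were 0.14 and 0.61 for wtf genes, 0.23 and 0.60 for antisense non-coding RNAs, 0.15 and 0.37 for DNA damage, 0.42 and 0.88 for mating genes and 1.38 and 2.54 for meiotic transcripts. Leaving out 1 library ended 6 of the 16 list calls in cph1Δ. Without wt replicate 2 the adjusted p was 0.640 for wtf genes, 0.0693 for antisense non-coding RNAs and 0.132 for DNA damage. It was 0.197 for wtf genes and 0.240 for antisense non-coding RNAs without cph1Δ replicate 2. Without cph1Δ replicate 1 it was 0.0823 for DNA damage and 0.0721 for thiamine. Without wt replicate 1 it was 0.188 for thiamine and 0.0997 for mating genes.

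Lists of abundant housekeeping transcripts were lower in cph1Δ without any member passing over all genes, and more so in 1 library. Replicate 2 of cph1Δ stood apart, with a TMM factor of 1.248, 5.21% of its counts in the top 10 genes against 7.12% in replicate 1, and 0.645% against 0.407% in non-coding RNAs. Against wt, medians in replicates 1 and 2 were -0.255 and -0.893 for ribosomal proteins, -0.22 and -0.65 for amino acid synthesis, -0.18 and -0.475 for the respiratory chain, -0.42 and -0.66 for histones and -0.46 and -0.996 for purine synthesis. The 114 ribosomal protein genes had a median of -0.56 (camera adjusted p = 2.5e-16; adjusted p = 0.577 with an estimated correlation) and 0 members past the test over all genes or when adjusted over the list alone; rps29 had -0.64 ± 0.22 and rpl2001 -0.79 ± 0.29. The 42 amino acid synthesis genes had a median of -0.43, with 0 members past either test (camera adjusted p = 4.9e-05; adjusted p = 0.555 with an estimated correlation). The 49 genes of the respiratory chain and ATP synthase had -0.27, also with 0 (camera adjusted p = 0.00191; adjusted p = 0.577 with an estimated correlation). Examples are cys11 at -0.80 ± 0.22 and atp4 at -0.73 ± 0.28. None of 9 histone genes passed over all genes and 2 were lower when adjusted over the list alone. The median was -0.52 and hht3 stood at -0.93 ± 0.28 (camera adjusted p = 0.00191; adjusted p = 0.523 with an estimated correlation). Of 8 purine synthesis genes, 0 passed over all genes and 3 were lower when adjusted over the list alone. The median was -0.73 and ade10 stood at -0.91 ± 0.26 (camera adjusted p = 0.00398; adjusted p = 0.459 with an estimated correlation). In the phosphate list pho84 and pho1 fell among 6 genes, 3 when adjusted over the list alone, with a median of -0.57 (camera adjusted p = 0.00191; adjusted p = 0.459 with an estimated correlation). Against matched random lists the histones lay at percentile 16.85 (matched median -0.405) and the respiratory chain at 8.91. Ribosomal proteins, amino acid synthesis and purine synthesis lay at percentile 0, with matched medians of -0.431, -0.215 and -0.237. Since level also varies within the matching bins, these percentiles cannot separate the lists from a trend with level. Beside these counts of 0 from edgeR, 1180 genes of the whole comparison had an unadjusted p under 0.05, and DESeq2 called 490 after adjustment.

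Of 135 subtelomeric genes, those within 100 kb of an end of chromosome I or II, 1 was higher and 5 were lower in cph1Δ, with 1 and 8 when adjusted over the list alone and a median of -0.18 (camera adjusted p = 0.00847; adjusted p = 0.663 with an estimated correlation). Replicates 1 and 2 of cph1Δ had medians of -0.26 and 0.06 against wt and 0.301% and 0.715% of counts in these genes. The list did not pass without cph1Δ replicate 1 (adjusted p = 0.199) or without wt replicate 1 (adjusted p = 0.453). Of the genes that fell, pho84 and pho1 also belong to the phosphate list, and SPAC186.02c went from 26 and 30 counts in wt to 2 and 2 in cph1Δ. Among transcription elongation factors and histone chaperones, the remodeller genes hrp3 (0.99 ± 0.24) and fft2 (0.64 ± 0.16) rose out of 24, 3 when adjusted over the list alone, and the list did not pass (median 0.28, camera adjusted p = 0.138). Of the 5 tested genes of Clr6 complex II and set2 other than cph1, pst2 rose (0.78 ± 0.16), 2 rose when adjusted over the list alone, and the list did not pass (median 0.40, camera adjusted p = 0.0684). The coding genes next to cph1 (5 tested, 1 higher) did not pass either, with a median of 0.31 (camera adjusted p = 0.392). Also without a pass were Clr6 complex I (median 0.45), copper and zinc (-0.27), general stress (0.21), heat shock chaperones (-0.22), the mitochondrial ribosome (-0.09) and oxidative stress and drug efflux (0.19). Others were S-phase targets of MBF (0.32), nitrogen starvation (0.66), mitosis and cell separation (0.21), flocculation (-0.50) and non-coding RNAs as a whole (0.31). The median and the mean or the test went opposite ways for glucose-repressed genes and hexose transporters (median -0.20, mean 0.12), the proteasome (median 0.03, test downward), iron uptake (median -0.0040, mean 0.08) and ribosome biogenesis (median -0.03, mean 0.01), none of which passed. With an estimated correlation 0 of the 34 lists passed, against 16 with the preset one. The number of calls rested on single libraries, at 41 without wt replicate 2 and 80 without cph1Δ replicate 2, and fitting the 4 compared libraries alone gave 168. DESeq2 called 490 genes, 329 higher and 161 lower, so the share of higher calls was 67.1% against 94.4% in edgeR and 93.7% in edgeR with RLE scaling.

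Deletion of cph2, the partner subunit, was also followed by more rises than decreases. The kinase gene mek1 rose by 2.80 ± 0.41, rec8 by 2.59 ± 0.48, the DNA translocase gene rhp1602 (SPBC582.10c, chromosome II, 436090 to 439017) by 2.27 ± 0.23 and vps1301 by 2.25 ± 0.22. The gene ftm4, for a protein with transmembrane helices, fell by 4.75 on the log2 scale (SE 0.96; SPAC750.05c, chromosome I, 5565881 to 5567337), from 249 and 172 counts to 10 and 7. The M-factor pheromone precursor gene mfm2 (SPAC513.03, chromosome I, 2912762 to 2913270) fell by 2.35 (SE 0.51), and pho84 by 1.94 (SE 0.29). In all, 310 genes differed between cph2Δ and wt (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 264 higher and 46 lower, 160 of them by at least 2-fold, 128 higher and 32 lower.

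Other named rises in cph2Δ were SPBC609.01 (2.57 ± 0.30), SPBC8E4.05c (2.20 ± 0.32), SPBC1773.13 (2.09 ± 0.23) and spo5 (2.08 ± 0.50). Named decreases were the non-coding RNAs SPNCRNA.1463 (chromosome II, 1776955 to 1778833; -4.11 ± 0.73) and SPNCRNA.963 (chromosome I, 4140077 to 4141041; -2.26 ± 0.44). The others were SPAPB1A11.02 (-3.85 ± 0.98), SPBPB10D8.01 (-2.73 ± 0.43) and SPAC2H10.01 (-2.67 ± 0.63, again with 5070 counts in 1 wt library against 759 in the other). The non-coding RNA prl37 had 0 counts in cph2Δ and 35 in wt, at least 13.03-fold lower against a floor of 3 counts over the group. Intervals and floors of this kind cover counting error only. In wt2, the other parent, prl37 had 2 counts. SPBPB10D8.01 (-3.16) and ftm4 (-2.56, not past the test) were also lower in wt2 than in wt. Of the genes named here, vps1301, SPBC609.01, rhp1602, SPBC8E4.05c, SPBC1773.13, spo5, SPNCRNA.1463, SPAPB1A11.02, SPBPB10D8.01 and pho84 share exon positions with another gene and are uncertain, as are mit1, rdp1, dcr1, cph1 and rpp202.

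The heterochromatin and RNA interference list was higher in cph2Δ too, with 5 of 16 members higher, 9 when adjusted over the list alone, and a median of 0.67 (camera adjusted p = 2.9e-06; adjusted p = 0.470 with an estimated correlation). Members that rose included mit1 (1.69 ± 0.24), rdp1 (edgeR adjusted p = 0.0034) and dcr1 (0.99 ± 0.16). Random lists matched in length and level to this list had a median of 0.35, and it lay at percentile 98.68 of them. Of 10 meiotic transcripts 3 rose, namely mek1, rec8 and spo5, and 5 when adjusted over the list alone. The median was 0.65 (camera adjusted p = 0.00893; adjusted p = 0.713 with an estimated correlation). The 13 Tf2 copies had a median of 1.52 with 3 higher, 4 when adjusted over the list alone, such as Tf2-11 (2.96 ± 0.44) and Tf2-2 (1.84 ± 0.47), each uncertain as a copy (camera adjusted p = 4.8e-05; adjusted p = 0.470 with an estimated correlation). The 5 tested genes of Clr6 complex II and set2 other than cph2 had a median of 0.48. Of them 0 passed over all genes and 3 were higher when adjusted over the list alone, with cph1 at 0.67 ± 0.19 and pst2 at 0.60 ± 0.16 (camera adjusted p = 0.0258; adjusted p = 0.470 with an estimated correlation).

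Of the 135 subtelomeric genes, 11 were lower and 1 higher in cph2Δ, over all genes and when adjusted over the list alone. The median was -1.08, the same with 7 genes of 0 counts at their bound (camera adjusted p = 4.1e-10; adjusted p = 0.470 with an estimated correlation). Besides ftm4, SPBPB10D8.01 and pho84, the members that fell included SPAC186.02c, from 26 and 30 counts to 2 and 4, and pho1 (-1.75 ± 0.29). These genes also spread between replicates, with a median level of 1.99 CPM in cph2Δ replicate 1 and 0.678 CPM in replicate 2, against 4.16 CPM and 2.11 CPM in wt. In wt2, the other undeleted parent, it was 1.77 CPM and 1.05 CPM, and the fitted median of wt2 against wt was -0.745. The level in wt thus stood above that in wt2 as well. In the phosphate list pho84 and pho1 fell among 6 genes, 3 when adjusted over the list alone, with a median of -0.52 (camera adjusted p = 6.7e-04; adjusted p = 0.470 with an estimated correlation). Of 599 non-coding RNAs 7 rose and 8 fell, or 3 and 2 when adjusted over the list alone. The median was -0.23 (camera adjusted p = 0.00999; adjusted p = 0.771 with an estimated correlation), from 0.05 in replicate 1 and -0.52 in replicate 2 against wt; SPNCRNA.307 had 3.71 ± 0.72 and SPNCRNA.359 rose from 2 and 2 counts to 37 and 54. Of 9 histone genes 0 passed over all genes and 5 were lower when adjusted over the list alone. The median was -0.66 and hta2 stood at -0.89 ± 0.24 (camera adjusted p = 0.00212; adjusted p = 0.482 with an estimated correlation). The 49 respiratory chain genes had a median of -0.22 with 0 members past either test and qcr1 at -0.86 ± 0.29 (camera adjusted p = 0.0212; adjusted p = 0.713 with an estimated correlation). The 114 ribosomal protein genes had -0.19, also with 0, and rpp202 stood apart at 0.97 ± 0.28 (camera adjusted p = 0.0258; adjusted p = 0.891 with an estimated correlation). Random lists matched in length and level had a median of -0.23, so this list lay at percentile 80.0 of them and did not stand below its matched genes. Leaving out 1 library ended 5 of the 10 list calls in cph2Δ. Without wt replicate 1 the adjusted p was 0.414 for non-coding RNAs and 0.0912 for the Clr6 complex II and set2 genes, and without cph2Δ replicate 2 it was 0.838 and 0.0769. Without wt replicate 2 it was 0.571 for ribosomal proteins and 0.205 for meiotic transcripts, and without cph2Δ replicate 1 it was 0.945 and 0.0517. For the respiratory chain it was 0.205 without wt replicate 2 and 0.0930 without cph2Δ replicate 2. Subtelomeric medians were -0.36 in replicate 1 and -1.44 in replicate 2. At an unadjusted p under 0.05 edgeR counted 1192 genes in this comparison.

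Between the mating-type loci mat1 (chromosome II, 2114219 to 2115027) and mat3 (2132586 to 2133394), the 6 tested genes had a median of 1.34 in cph2Δ, against -0.11 for 19 genes within 20 kb outside, a region singled out after its values were seen. The proteasome subunit gene rpt6 (2121444 to 2122817) rose by 1.70 ± 0.26 (edgeR adjusted p = 0.0040), and SPBC23G7.14 (2126496 to 2128132), which shares exon positions with another gene, rose by 2.00 ± 0.24 (edgeR adjusted p = 0.0012). SPBC23G7.13c (2.28 ± 0.85), rpp202, SPNCRNA.388 (0.83 ± 0.24) and SPBC23G7.10c (0.62 ± 0.52) were higher in the fit without passing. Of these, SPBC23G7.13c and rpp202 also share exon positions with another gene and are uncertain. The median of the same 6 genes was 0.35 in cph1Δ and 0.43 in set2Δ. In cph1Δ SPBC23G7.10c rose by 2.02 ± 0.53 (edgeR adjusted p = 0.0486), with 54.8 CPM and 236 CPM in cph1Δ against 46.4 CPM and 25.3 CPM in wt.

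**Figure D2:**
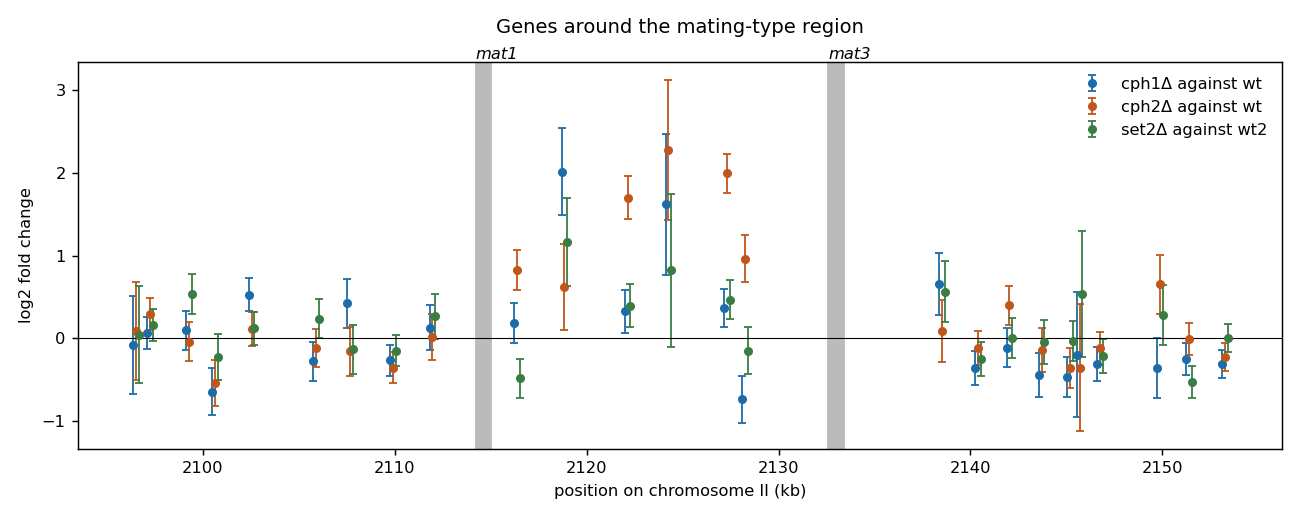
Fitted log2 fold change ± SE of each tested gene by position on chromosome II around mat1 and mat3 (grey bars), in cph1Δ, cph2Δ and set2Δ. In cph2Δ the 6 genes between the bars have a median of 1.34, against -0.11 for the 19 genes outside.

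Lists that did not pass in cph2Δ had medians of -0.11 for amino acid synthesis, -0.48 for copper and zinc, 0.24 for DNA damage, -0.15 for general stress, -0.08 for glucose-repressed genes and hexose transporters, 0.48 for heat shock chaperones and -0.10 for iron uptake. Mating genes had 0.26, mitosis and cell separation 0.38, nitrogen starvation 0.49 and oxidative stress -0.16. They were 0.23 for the proteasome, -0.41 for purine synthesis, 0.32 for S-phase targets, 0.44 for thiamine, 0.23 for elongation factors, -0.28 for wtf genes and 0.49 for the neighbours of cph2. Median and mean differed in sign for Clr6 complex I, flocculation, the mug and meu families, antisense non-coding RNAs and ribosome biogenesis. With an estimated correlation 0 of the 34 lists passed, against 10 with the preset one. The number of calls was 64 without wt replicate 2, 91 without cph2Δ replicate 2 and 121 with the 4 compared libraries alone. DESeq2 called 538 genes, 337 higher and 201 lower, so 62.6% were higher against 85.2% in edgeR.

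Deletion of set2 was followed by strong derepression near the ends of chromosomes I and II. The urea transporter genes SPAC869.03c (chromosome I, 5512757 to 5514865) and SPBPB8B6.02c (chromosome II, 44694 to 46836) rose by 6.65 ± 0.73 and 7.21 ± 1.06 on the log2 scale. The asparaginase genes SPBPB21E7.09 (chromosome II, 75073 to 77625) and SPAC186.03 (chromosome I, 5535061 to 5536432) rose by 4.50 ± 0.34 and 5.67 ± 0.47. The gluconate transporter gene ght3 (SPAC1F8.01, chromosome I, 82746 to 84786) rose by 4.25 ± 0.38. These rises are against wt2, where the same genes stood lower than in wt. In wt2 against wt the values were -1.60 for SPAC869.03c, -2.47 for SPBPB8B6.02c, -2.525 for SPBPB21E7.09, -1.87 for SPAC186.03 and -1.62 for ght3. Only that of SPBPB21E7.09 passed the test. Against wt the rises of these genes were therefore smaller. Away from the ends, ght5 fell by 2.60 (SE 0.33), mfm2 by 2.20 (SE 0.49) and the alpha-glucanase gene agn2 (SPBC646.06c, chromosome II, 932654 to 934311) by 1.69 (SE 0.26). In all, 248 genes differed between set2Δ and wt2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 219 higher and 29 lower, 176 of them by at least 2-fold, 159 higher and 17 lower.

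Of 135 subtelomeric genes, 66 rose and 1 fell, 110 and 1 when adjusted over the list alone. The median was 3.55, or 3.39 with 5 genes of 0 counts at their bound (camera adjusted p = 1.1e-69; adjusted p = 0.0593 with an estimated correlation). The pseudogene SPBPB10D8.03 (chromosome II, 87727 to 89029) had 0 counts in wt2 and 667 in set2Δ, at least 206-fold higher (edgeR adjusted p = 5.3e-04). By the same floor SPBPB10D8.02c was at least 42.5-fold, SPBPB21E7.08 at least 12.3-fold and SPAC212.03 at least 10.5-fold higher. These bounds are against wt2 only, and the other parent had more counts. In wt SPBPB21E7.08 had 11 counts and SPAC212.03 had 14, against 40 and 34 in set2Δ. The fitted log2 fold change of wt2 against wt was -7.79 for SPBPB10D8.02c and -7.38 for SPBPB10D8.03, neither past the test. Against wt the rise of each of these genes was therefore smaller. The gene ftm7 (chromosome II, 4501956 to 4502396) had 2 counts in wt2 and 240 in set2Δ, a ratio of 111 (95% counting interval 30.4 to 921). Other large rises were those of the pseudogene SPBC1348.11 (7.97 ± 1.13), SPBPB2B2.06c (6.24 ± 0.56) and the transcription factor gene SPBC1348.12 (chromosome II, 35112 to 36589; 4.22 ± 0.35). On an unplaced contig SPBC460.04c (14073 to 15248) and SPBC460.05 (16470 to 18062) rose by 6.61 ± 0.58 and 6.61 ± 0.86. The rise held at each of the 4 arms, with medians of 2.59 at I left (38 genes, 16 higher), 3.56 at I right (40, 18 higher), 4.21 at II left (30, 21 higher) and 2.46 at II right (27, 11 higher and 1 lower). The median subtelomeric level was 17.8 CPM and 18.6 CPM in the set2Δ libraries, against 1.77 CPM and 1.05 CPM in wt2. In wt it was 4.16 CPM and 2.11 CPM.

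**Figure D3:**
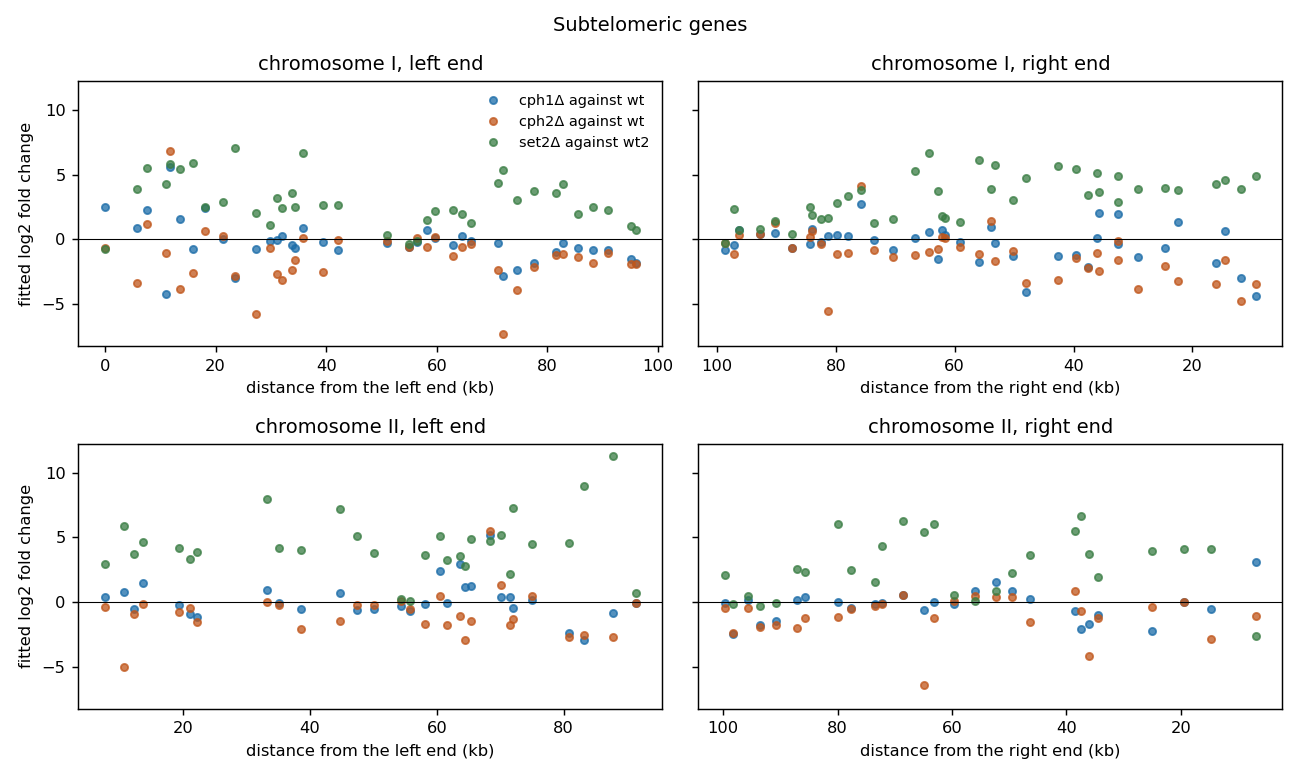
Fitted log2 fold change of each subtelomeric gene against its distance from the left or right end of chromosome I or II, in cph1Δ, cph2Δ and set2Δ. Medians over the 135 genes are -0.18, -1.08 and 3.55.

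Lower in set2Δ were also the phospholipase gene plb2 (-1.91 ± 0.39), the non-coding RNAs SPNCRNA.1008 (-1.57 ± 0.36) and SPNCRNA.1381 (-1.30 ± 0.31), the polyamine transporter gene SPBC409.08 (-1.52 ± 0.34) and SPAC27D7.11c (-1.35 ± 0.30). Of 10 flocculation and cell surface genes 3 rose, 5 when adjusted over the list alone. The median was 0.67 (camera adjusted p = 0.00137; adjusted p = 0.698 with an estimated correlation), and the 3 were pfl7 (5.02 ± 0.77), pfl9 (3.04 ± 0.51) and pfl5 (1.46 ± 0.26). For pfl7 the level was 1.70 ± 0.259 CPM in wt2, 55.2 ± 9.61 CPM in set2Δ and 24.7 ± 0.553 CPM in wt. Of 13 iron uptake genes 2 rose, 3 when adjusted over the list alone, namely abc3 (2.04 ± 0.29) and the ferrichrome synthetase gene sib1 (1.17 ± 0.20). The median was 0.70 (camera adjusted p = 0.0130; adjusted p = 0.698 with an estimated correlation). In the nitrogen starvation list isp4 (1.70 ± 0.31), isp5 (2.12 ± 0.40) and per1 (0.93 ± 0.19), all for uptake of amino acids or peptides, rose among 12 genes, 4 when adjusted over the list alone. The median was 0.43 (camera adjusted p = 0.0303; adjusted p = 0.698 with an estimated correlation). Of 16 heterochromatin and RNA interference factors 3 rose, 5 when adjusted over the list alone. The median was 0.42, with the HP1 gene chp2 at 1.06 ± 0.22 and mit1 at 1.01 ± 0.23 (camera adjusted p = 0.0130; adjusted p = 0.698 with an estimated correlation). This list lay at percentile 89.05 of random lists matched in length and level. Of 10 meiotic transcripts rec10 (1.75 ± 0.36) and mek1 (1.93 ± 0.41) rose, 4 when adjusted over the list alone. The median was 1.17 (camera adjusted p = 0.00341; adjusted p = 0.698 with an estimated correlation). The 13 Tf2 copies had a median of 1.33 with 1 higher in either test, Tf2-11 at 2.97 ± 0.44 and uncertain as a copy (camera adjusted p = 0.00341; adjusted p = 0.698 with an estimated correlation). Of 14 genes of mitosis and cell separation 0 passed over all genes and 2 were higher when adjusted over the list alone. The median was 0.49, and fkh2 stood at 0.78 ± 0.21 and eng1 at 0.93 ± 0.27 (camera adjusted p = 0.0130; adjusted p = 0.698 with an estimated correlation). The 114 ribosomal protein genes had a median of -0.23 and 0 members past either test, with rpp1 at -0.73 ± 0.24 (camera adjusted p = 2.4e-05; adjusted p = 0.745 with an estimated correlation). Medians against wt2 in replicates 1 and 2 of set2Δ were 0.31 and 1.12 for iron uptake, 0.13 and 0.68 for nitrogen starvation and 0.80 and 1.49 for Tf2 copies. Some lists were also lower in wt2 than in wt. Against wt instead of wt2, medians in replicates 1 and 2 of set2Δ were 0.28 and 0.55 for flocculation, -0.19 and 0.16 for iron uptake and -0.13 and -0.04 for mitosis and cell separation. Leaving out 1 library ended 5 of the 9 list calls. Without set2Δ replicate 2 the adjusted p was 0.204 for iron uptake, 0.293 for nitrogen starvation and 0.0774 for Tf2 copies. Without wt2 replicate 1 it was 0.0969 for iron uptake, 0.0595 for Tf2 copies, 0.0595 for heterochromatin factors and 0.0911 for mitosis and cell separation, and without wt2 replicate 2 it was 0.0749 for nitrogen starvation. At an unadjusted p under 0.05 edgeR counted 924 genes here. Exon positions are shared with another gene by plb2, SPNCRNA.1008, SPNCRNA.1381, pfl7, abc3, isp5, per1, mit1, rec10 and fkh2, whose values are uncertain. The chromosome end genes SPBPB10D8.02c and SPBPB21E7.08 overlap another gene in position and are uncertain too.

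The elongation and histone chaperone list did not pass in set2Δ, with 0 of 24 members past the test, a median of -0.02 and a mean of 0.06 (camera adjusted p = 0.723). Nor did the 5 tested genes of Clr6 complex II (median 0.42), the neighbours of set2 (0.52), non-coding RNAs (0.36, with 17 higher and 2 lower) or antisense non-coding RNAs (0.34). General stress (0.49), heat shock chaperones (0.67), glucose-repressed genes and hexose transporters (0.19), phosphate (-0.30) and histones (-0.26) did not pass either. Mating genes had a median of 0.13 and a mean of -0.16. With an estimated correlation 0 of the 34 lists passed, against 9 with the preset one. Fitting the 4 compared libraries alone gave 314 calls, 251 higher and 63 lower. DESeq2 called 357 genes, 298 higher and 59 lower, so 83.5% were higher against 88.3% in edgeR. Leaving out any of the 4 compared libraries lowered the number of calls, to 54 without wt2 replicate 2, 72 without wt2 replicate 1, 106 without set2Δ replicate 1 and 130 without set2Δ replicate 2.

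The cph1Δ and cph2Δ strains differed from each other at 3 genes, 2 of which were the deleted genes. Against cph2Δ, cph1Δ had cph1 at -5.20 ± 0.24 and cph2 at 5.09 ± 0.40. The other was SPBC23G7.14, between mat1 and mat3, at -1.63 ± 0.23 (edgeR adjusted p = 0.030). At an unadjusted p under 0.05 edgeR counted 351 genes, and DESeq2 called 15 after adjustment, 10 higher and 5 lower, so 66.7% were higher against 33.3% in edgeR. The lists higher in cph1Δ than in cph2Δ were non-coding RNAs (median 0.44, camera adjusted p = 2.1e-12), antisense non-coding RNAs (0.33), subtelomeric genes (0.54), meiotic transcripts (0.80), general stress (0.39), wtf genes (0.41), mating genes (0.29) and the mug and meu families (0.19). Those lower were ribosomal proteins (-0.37, camera adjusted p = 2.0e-17), amino acid synthesis (-0.28), heat shock chaperones (-0.69), flocculation (-0.38) and the proteasome (-0.20). No member of any of these passed over all genes, and with an estimated correlation 0 of 33 lists passed. The libraries numbered 2 were further apart than those numbered 1. Against wt, cph1Δ and cph2Δ had ribosomal protein medians of -0.255 and -0.307 in replicate 1 and -0.893 and -0.013 in replicate 2. For non-coding RNAs these were 0.11 and 0.05, then 0.44 and -0.52, for subtelomeric genes -0.26 and -0.36, then 0.06 and -1.44, and for amino acid synthesis -0.22 and -0.19, then -0.65 and 0.05. Replicate 2 of cph2Δ had 10.1% of its counts in the top 10 genes and 0.266% in non-coding RNAs, against 5.21% and 0.645% in replicate 2 of cph1Δ. Of the 13 lists 8 passed without cph2Δ replicate 2, 10 without cph1Δ replicate 2 and 11 without cph2Δ replicate 1.

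The effect of cph1 loss differed from that of set2 loss at 44 genes, 6 higher and 38 lower. The effect of cph2 loss differed from it at 64, 6 higher and 58 lower (edgeR quasi-likelihood test of the difference, Benjamini-Hochberg adjusted p under 0.05). The FAR complex gene csc2 (chromosome II, 1326004 to 1328707) differed by 1.94 ± 0.27 for cph1Δ and 2.00 ± 0.27 for cph2Δ. For sip1 the values were 1.31 ± 0.26 and 1.40 ± 0.26, and for the myosin V gene myo52 (chromosome III, 2224882 to 2229932) 1.19 ± 0.24 and 1.29 ± 0.24. The lifespan gene ecl1 differed by 2.05 ± 0.34 for cph1Δ, and agn2 by 1.79 ± 0.37 and SPBC23G7.14 by 1.53 ± 0.33 for cph2Δ; ecl1, sip1 and SPBC23G7.14 share exon positions with another gene and are uncertain. Among the most negative differences were genes at the chromosome ends, for example SPAC186.02c at -8.78 ± 0.74 for cph1Δ and SPAC186.03 at -8.79 ± 0.69 for cph2Δ. As a list, subtelomeric genes had a median difference of -3.17 for cph1Δ, with 1 higher and 26 lower, or 2 and 75 when adjusted over the list alone (camera adjusted p = 8.5e-88; adjusted p = 0.0391 with an estimated correlation). For cph2Δ it was -4.47, with 43 lower and 100 when adjusted over the list alone (camera adjusted p = 5.7e-105; adjusted p = 0.0254 with an estimated correlation). Lists with a positive difference for cph1Δ were mating genes (0.48), heterochromatin factors (0.41) and wtf genes (0.36), and those with a negative one were flocculation (-0.74), heat shock chaperones (-0.85), amino acid synthesis (-0.39), phosphate (-0.54) and ribosomal proteins (-0.33). The parents differed in the same direction in the last 5 lists, with medians in wt2 against wt of -0.505, -0.45, -0.22, -0.38 and -0.21. Such a gap between the parents is part of the difference of effects. Mating genes were likewise higher in wt2 than in wt, so their positive difference is not free of it. Subtelomeric genes had -0.745 and heterochromatin factors 0.025 in wt2 against wt. For cph2Δ flocculation (-0.61), general stress (-0.52), iron uptake (-0.94), phosphate (-0.86) and non-coding RNAs (-0.49) were negative, and wt2 against wt had -0.505, -0.23, -0.59, -0.38 and -0.14 in these. Of all these, only the subtelomeric list passed with an estimated correlation. Leaving out 1 library ended 6 of the 9 list calls for cph1Δ and 5 of the 6 for cph2Δ.

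The parent strains differed from each other at 10 genes, 3 higher and 7 lower in wt2 than in wt. The marker gene ura4 (chromosome III, 115589 to 116726) had 3045 counts in wt2 and 0 in wt, at least 927-fold, and the non-coding RNA SPNCRNA.129 beside it (115394 to 115476) had 792 and 0, at least 241-fold. The adjacent tam14 was higher by 1.14 ± 0.19. Lower in wt2 were SPBPB10D8.01 (-3.16 ± 0.44), SPBPB21E7.09 (-2.53 ± 0.33), the phosphate transporter gene pho841 (-2.20 ± 0.25), SPCC569.05c (-1.86 ± 0.25), abp2 (-1.84 ± 0.29), pfl3 (-1.55 ± 0.20) and the amine oxidase gene cao1 (-1.09 ± 0.17), of which SPBPB10D8.01, SPCC569.05c and abp2 share exon positions with another gene. Of 33 lists 11 passed, with mating genes higher (median 0.40). Lower medians were those of subtelomeric genes (-0.75), iron uptake (-0.59), flocculation (-0.51), heat shock chaperones (-0.45), mitosis and cell separation (-0.41), phosphate (-0.38), oxidative stress (-0.28), amino acid synthesis (-0.22), ribosomal proteins (-0.21) and ribosome biogenesis (-0.18). None passed with an estimated correlation. DESeq2 called 64 genes, 8 higher and 56 lower, so 12.5% were higher against 30% in edgeR.

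Many of the genes that rose in 1 deletion also rose in another. Of those higher in cph1Δ and in cph2Δ, 196 were common, where 14.015 were expected from independent lists (Fisher exact p = 9.6e-229), and 9 of those lower, where 0.145 were expected. Both comparisons used the same wt libraries. In 25 simulated draws of unchanged groups with these libraries shared, a mean of 0.16 and at most 1 higher genes were common. The draws held no changed genes and no shift of a whole library. They therefore cannot show how far the shared wt libraries raised the overlap of 196. With set2Δ, 81 higher genes were common to cph1Δ (11.6 expected, Fisher exact p = 1.8e-50) and 73 to cph2Δ (11.4 expected, Fisher exact p = 3.9e-42). Of the genes lower in cph1Δ, 2 were lower and 4 higher in set2Δ, and of those lower in cph2Δ 2 were lower and 9 higher. Correlations of log2 fold changes across genes, which are not independent replicates, were 0.617 between cph1Δ and cph2Δ (0.514 in the simulation with shared wt libraries), 0.206 between cph1Δ and set2Δ and 0.004 between cph2Δ and set2Δ. In all 3 deletions 68 genes rose and 1, SPACUNK4.15, fell (-0.72, -0.78 and -0.78). Common rises were ranked by the smallest of the 3 log2 fold changes of a gene. The largest common rises, in the order cph1Δ, cph2Δ and set2Δ, were SPNCRNA.307 (3.09, 3.71 and 3.78; in set2Δ from 2 counts in wt2 to 34, a ratio of 15.7 with a 95% counting interval of 4.03 to 135), Tf2-11 (2.55, 2.96 and 2.97), the fumarate lyase family gene SPBC8E4.05c (2.26, 2.20 and 3.43), the aromatic aminotransferase gene SPBC1773.13 (2.15, 2.09 and 2.17) and the DNA translocase gene rdh54 (2.02, 2.08 and 2.64).

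In cph1Δ and cph2Δ the median log2 fold change of coding genes was highest in the longest of 7 bins of exon length. Across the 4409 coding genes, which are not independent replicates, the rank correlation of log2 fold change with exon length was 0.206 in cph1Δ, 0.153 in cph2Δ and 0.126 in set2Δ, and with the parent's level -0.535, -0.267 and -0.339. Between the parents it was 0.0707 with length and -0.129 with level. In cph1Δ the median ran from -0.16 for genes under 1 kb to 0.43 for 121 genes of 5 to 7 kb and 0.67 for 36 genes over 7 kb, of which 11 rose. Over 7 kb the median was 0.61 in cph2Δ, where 13 rose, and 0.17 in set2Δ, where 7 rose; over the library pairs of set2Δ it ran from -0.03 to 0.435, and genes of 4 to 5 kb had 0.20. The 157 coding genes over 5 kb, made a list after the data were seen, had 43, 42 and 19 members higher in cph1Δ, cph2Δ and set2Δ, and medians of 0.45, 0.34 and 0.14. Long genes of high level did not rise. Over 4 kb, medians in the lowest tercile by level in the other parent were 0.80, 0.53 and 0.465, and in the highest -0.12, -0.03 and -0.04. Gaps to level-matched genes under 2 kb were 0.476, 0.315 and 0.243 (SD over library pairs 0.107, 0.111 and 0.054), so set2Δ had one too.

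**Figure D4:**
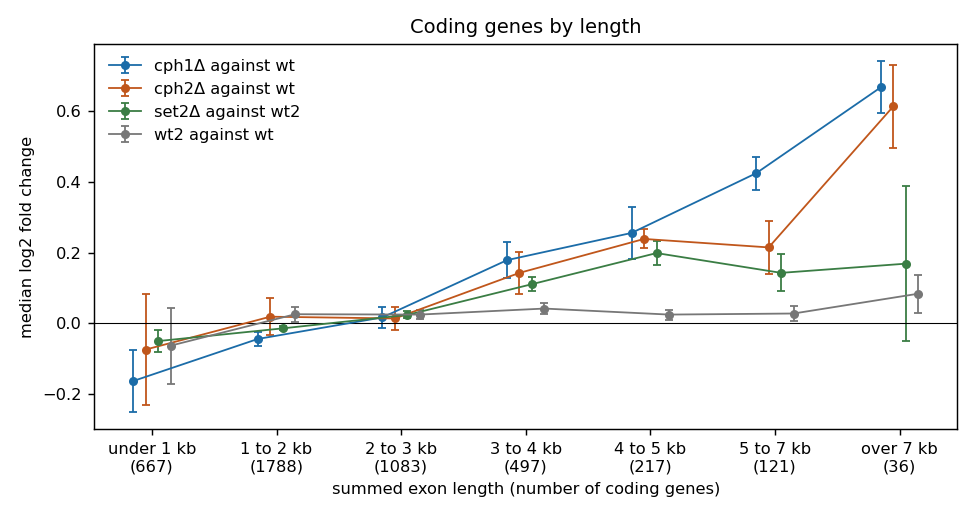
Median log2 fold change of coding genes in 7 bins of exon length, with the SD over library pairs, for the 3 deletions and for wt2 against wt. In the longest bin the medians are 0.67, 0.61, 0.17 and 0.08.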

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

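A test of the difference between effects singled out the following values, and the tests of explanations given here were all chosen only after the results were seen. Between cph1Δ and cph2Δ 3 genes differed, among them SPBC23G7.14 at -1.632. The effect of cph1 loss differed from that of set2 loss at 44 genes. Of these, ecl1 (2.053), csc2 (1.935), sip1 (1.308) and myo52 (1.188) were higher, and SPBPB10D8.03 (-12.112), SPAC750.06c (-9.299), SPAC186.02c (-8.784), SPBC460.05 (-8.469) and SPAC869.01 (-7.864) lower. The effect of cph2 loss differed from that of set2 loss at 64 genes, with csc2 (2.003), agn2 (1.785), SPBC23G7.14 (1.527), sip1 (1.397) and myo52 (1.287) higher and SPBPB10D8.03 (-14.023), SPBC460.05 (-9.211), SPAC186.03 (-8.789), SPBPB8B6.02c (-8.678) and ftm4 (-8.665) lower. Fitted values of genes with counts near 0 depend on the prior count and are not measured folds.

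List medians also differed between the effects with the preset correlation, but with an estimated one only the subtelomeric list passed in each. For cph1Δ against set2Δ they were -3.171 for subtelomeric genes, -0.848 for heat shock chaperones, -0.743 for flocculation, -0.535 for phosphate, -0.393 for amino acid synthesis, -0.325 for ribosomal proteins, 0.357 for wtf genes, 0.406 for heterochromatin factors and 0.482 for mating genes. For cph2Δ against set2Δ they were -4.474 for subtelomeric genes, -0.935 for iron uptake, -0.858 for phosphate, -0.613 for flocculation, -0.515 for general stress and -0.487 for non-coding RNAs.

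The rise of subtelomeric genes in set2Δ was weighed against 3 technical explanations. If low wt2 libraries made the whole rise, set2Δ would show none against wt, but the medians against wt were 2.181 and 2.142. Against wt2 they were 3.286 and 3.347, and the fitted median of wt2 against wt was -0.745. A part of the rise against wt2 thus goes with the lower level in wt2. If few reads made the rise, the 56 genes with at least 5 CPM in wt, which is not part of the comparison, would not show it, but their median was 2.084 (SD over library pairs 0.206). An extra copy of the chromosome ends would centre the values on 1, but the lowest median over library pairs was 2.832. These results count against each of the 3 explanations as the source of the whole rise, but not of a part of it. Other explanations remain, among them a biological effect of set2 loss, and were not tested.

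The rise of long coding genes in cph1Δ and cph2Δ was weighed in the same way. A length bias of the libraries would set genes over 4 kb apart from short genes of the same level by a gap alike at every level; between the lowest and highest tercile it differed by 0.456 in cph1Δ (SD over library pairs 0.162) but only 0.274 in cph2Δ (SD 0.084). A low level of long genes alone would shift matched short genes as much, but the smaller gap to them was 0.315. If only the wt libraries stood low, the rise would vanish against wt2, but the lowest median of genes over 7 kb in a cph1Δ or cph2Δ library was 0.443. Relative to the mean of the 5 groups, medians of these genes were -0.175 and -0.192 in wt2. In wt they were -0.283 and -0.347. The comparison with wt2 therefore cannot address a low level shared by both parents. Since 0.274 lay within the limit of 0.2 plus the SD, a length bias remains open, and a joint trend with length and level, and RNA integrity, were not tested.

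The genes between mat1 and mat3 in cph2Δ were weighed against a chance run and an extra copy. Over runs of 2 to 6 coding genes, a run as unusual appeared in 14 of 1000 shuffled gene orders, but in 548 when only 1 of 2 overlapping genes was kept. With 1 extra copy the values would lie around 1, and their chi-square p was 8.4e-05 for the 6 genes. It was 0.0652 without SPBC23G7.14, which shares exon positions with another gene. Neither a chance run nor 1 extra copy is excluded, and no biological explanation was tested.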

How the results depend on the processing

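No call of a gene changed sign under any alternative, and RLE scaling and coding genes only kept every count of calls within 1.5 times. Leaving out a library assumes that the lone sample of its group varies like the other groups. Except where fewer libraries were fitted, the cause of a change was not tested. Of 150 named calls, 54 held under every alternative.

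With the compared libraries only, calls were 168 in cph1Δ, 121 in cph2Δ and 4 between the parents. With DESeq2 they were 490 in cph1Δ, 538 in cph2Δ, 15 between cph1Δ and cph2Δ, 85 and 110 for the differences of cph1Δ and cph2Δ from set2Δ, and 64 between the parents. Without a filter they were 8 between cph1Δ and cph2Δ, 69 for the difference of cph1Δ from set2Δ and 32 between the parents. Lists passing with an estimated correlation were 0 in cph1Δ, 0 in cph2Δ, 0 in set2Δ, 0 between cph1Δ and cph2Δ, 1 and 1 for the differences, and 0 between the parents. With fry they were 6 in cph1Δ, 2 in set2Δ, 0 between cph1Δ and cph2Δ, 1 and 1 for the differences, and 0 between the parents.

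Shared lower genes without a filter were 23 for cph1Δ and cph2Δ, 8 for cph1Δ and set2Δ, 5 for cph2Δ and set2Δ and 5 for all 3; with DESeq2 they were 77, 10, 13 and 9. Of the alternatives chosen after seeing the data, the level in the other parent gave a correlation of -0.2916 in set2Δ, and leaving out the subtelomeric genes gave 152 calls in set2Δ. The libraries share only a number; with a replicate block, calls were 260 in cph1Δ, 275 in cph2Δ and 227 in set2Δ, shared lower genes were 1 for cph1Δ and set2Δ and 0 for all 3, and correlations of the paired differences ran from -0.413 to 0.264.

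Leaving out 1 library reversed the sign of some fitted values. For cph2 in cph1Δ the value ran from -0.014 (without cph1Δ replicate 2) to 0.640. The ribosomal protein median in cph2Δ ran from -0.401 to 0.039 (without wt replicate 2). Without wt replicate 1, the subtelomeric median in cph1Δ was 0.206 instead of -0.175. That of non-coding RNAs in cph2Δ was then 0.020 instead of -0.231. Without wt replicate 2, the flocculation median for the difference of cph2Δ from set2Δ was 0.088 instead of -0.613. Calls in cph1Δ ran from 41 (without wt replicate 2; 80 without cph1Δ replicate 2) to 311, and at 2-fold from 41 (74 without cph1Δ replicate 2) to 239. In cph2Δ they ran from 64 (without wt replicate 2; 91 without cph2Δ replicate 2) to 440, and at 2-fold from 62 to 318 (without cph2Δ replicate 1; 84 without cph2Δ replicate 2). In set2Δ they ran from 54 (without wt2 replicate 2; 72 without wt2 replicate 1, 106 without set2Δ replicate 1) to 130 (without set2Δ replicate 2), and at 2-fold from 54 (72 without wt2 replicate 1, 103 without set2Δ replicate 1) to 121. Between cph1Δ and cph2Δ calls ran from 2 to 26 (without cph1Δ replicate 1; 23 without cph2Δ replicate 1). The difference of cph1Δ from set2Δ had 20 (without set2Δ replicate 2; 26 without wt replicate 1, 28 without cph1Δ replicate 2) to 45, and that of cph2Δ 20 (without set2Δ replicate 2; 24 without wt replicate 1, 40 without cph2Δ replicate 2, 41 without wt2 replicate 2) to 102 (without cph2Δ replicate 1). The parents differed at 6 (without wt2 replicate 2) to 12. Lists for the 2 differences ran from 5 (without wt replicate 2 or cph1Δ replicate 2) to 13 and from 2 (without wt2 replicate 1; 3 without cph2Δ replicate 1 or set2Δ replicate 2) to 8.

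Shared higher genes ran from 34 (without wt replicate 2) to 168 for cph1Δ and cph2Δ, 15 (without wt2 replicate 2) to 88 for cph1Δ and set2Δ, 13 (without wt2 replicate 1) to 75 for cph2Δ and set2Δ and 13 (without wt2 replicate 1) to 71 for all 3. For cph1Δ and cph2Δ they were 71 without cph1Δ replicate 2 and 82 without cph2Δ replicate 2. Each overlap with set2Δ moved by over 1.5 times without wt replicate 2, replicate 2 of the cph strain, or any library of wt2 or set2Δ. Shared lower genes ran from 3 to 32, 0 to 9, 0 to 7 and 0 to 7, each highest without wt replicate 1. The correlation with length ran from 0.1802 to 0.2107 in cph1Δ, from 0.0803 (without cph2Δ replicate 1) to 0.2444 (without cph2Δ replicate 2) in cph2Δ and from 0.0911 to 0.1446 in set2Δ. That with level ran from -0.5815 to -0.3743 in cph1Δ, from -0.3779 to -0.1637 (without cph2Δ replicate 1; -0.1775 without wt replicate 2) in cph2Δ and from -0.3662 to -0.293 in set2Δ.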
